A study of Glycine max with 4 samples.

How the data were processed

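Leaf RNA was measured by RNA-seq in 4 groups: Pana control, Pana drought, PI 567690 control and PI 567690 drought. Each group is 1 GEO sample with 3 columns in 1 table, so 12 libraries entered, each placed in its group by the line and treatment in its column name. The series design text calls the replicates biological and says that the RNA was multiplexed on an Illumina HiSeq instrument. The labels do not say which plants each column came from, so p-values measure the spread between these libraries.

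The submitters' processing notes name FastQC, TopHat 1.4.1, Cufflinks and Cuffdiff, with no role or order, and the design text names TopHat followed by Cufflinks and also BWA followed by ANOVA. The genome build and annotation are not given in the sources used here. The deposited values were taken as FPKM, reads relative to the length of the gene model and to the mapped reads of the library, as computed by the authors. The table does not name the unit: it was read from values that are not whole, from column totals that differ between libraries, and from low values that are multiples of a step that depends on the gene. FPKM normalization is relative, so a few abundant genes that take more reads lower all others. Reads shared by near-identical gene copies, which are common in soybean, could have been split between them by the authors' software, and values of such copies are uncertain.

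Gene identifiers were used as the table gives them. None of them (0 of 54175) matched the RefSeq name table used here, which lists 59048 genes of assembly Glycine_max_v4.0, so no gene names or descriptions are given and the 47 gene lists fixed for this work could not be applied. The named genes were to be the largest rises and falls in each comparison among genes past the threshold, with a mean level above the median of the tested genes and, except for the difference of responses, with no overlap between the replicates of the compared groups. Because no description was found for any gene, that requirement was dropped and the number was limited to 2 rises and 2 falls per comparison.

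Genes with at least 1 FPKM in at least 3 libraries (32697) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (trend on mean expression, prior degrees of freedom 3.42, residual degrees of freedom 8), with 1 coefficient per group over all 12 libraries and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The contrasts were drought against control in each line, the difference of these 2 effects (PI 567690 minus Pana), and PI 567690 against Pana under control and under drought. The 2 groups of a contrast with 3 libraries each make 10 splits, so no permutation of labels alone could give a share under 0.1. In data simulated for the PI 567690 contrast on 32697 genes, 12% of genes with a log2 change of 1 were called. Of those with a log2 change of 2, 60% were called, and there were 6 false calls. The simulation gave each gene 1 SD for all 12 libraries, with independent noise. It leaves out the wider spread in Pana and the near-identity of PI 567690 drought libraries 2 and 3. These figures need not hold for the real fit.

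Whole reads were recovered for 29515 (70.8%) of the 41685 genes above 0 in at least 8 libraries, within a tolerance of 0.06 reads. Their sums, 5835012 to 20222377 reads per library, are lower bounds of the depth. They served for the chi-square comparison of replicates and for 1 alternative fit with limma's voom. Line-marker genes of a library were those whose log2(FPKM + 0.25) parted all other libraries of the 2 lines by at least 2-fold. A position on the scale between the mean levels of the lines counted as the level of PI 567690 below 0.25 and as that of Pana above 0.75. The shares of RNA of PI 567690 that these levels need or allow were read from mixtures of the mean levels of the lines in steps of 1%, at the lower 95% limit of each percentage of genes. Runs along the gene identifiers were tested with 100000 permutations and neighbouring calls with 1000 shuffles.

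The alternatives covered scaling to an equal median ratio, the filter on low values, the pseudocount, the libraries in the fit, the thresholds, a block for the replicate number and each library left out. Analyses were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.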

Results

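Leaf RNA of 2 soybean (Glycine max) lines was compared under well-watered conditions and after 15 days without adequate water. Pana is labelled drought susceptible and PI 567690 drought tolerant, and the title of the series sets the lines apart by canopy wilting, the drooping of the leaf canopy as the soil dries. Stress began at the V5 vegetative stage in pots of soil and sand, and leaves were taken at the R2 reproductive stage. Each of the 4 groups (Pana control, Pana drought, PI 567690 control, PI 567690 drought) held 3 libraries, which the design text of the series calls biological replicates. Expression was given as FPKM for 54175 gene models, of which 32697 reached 1 FPKM in at least 3 of the 12 libraries and were tested. The gene models appear by their identifiers, because the files do not pair them with gene names and none matched the name table used here.

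The depth of the libraries could be read in part from the steps in their FPKM values. Whole reads were recovered for 29515 gene models, and they summed to 5835012 reads in Pana control library 1, the lowest, and to 20222377 reads in PI 567690 control library 2, the highest. The size of the steps itself ranks the libraries otherwise: relative to Pana drought library 3, the deepest by this measure, it puts PI 567690 drought library 1 at 48.3%, PI 567690 control library 1 at 50.3% and Pana control library 1 at 50.5%. Genes with a mean of 1 to 2 FPKM over the libraries rested on a median of 15 reads in Pana control library 1 and of 67 reads in PI 567690 control library 2. Pana control library 1 also listed 15657 gene models at 0 and 24623 at or above 1 FPKM, against 27035 to 29853 at or above 1 FPKM in the other libraries. PI 567690 control library 1 and drought library 1, of similar depth by the steps, had medians of 34 and 32 reads. They listed 10978 and 11547 gene models at 0. Depth by the steps alone therefore does not account for the low values of Pana control library 1. Replicates spread more widely on the log2 scale in Pana than in PI 567690: the median SD of a gene was 0.426 in Pana control, 0.427 in Pana drought, 0.139 in PI 567690 control and 0.213 in PI 567690 drought (n = 3 each).

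The libraries did not separate fully by line and treatment. The first principal component held 41.5% of the variance and placed PI 567690 drought and Pana drought libraries 1 and 2 apart from the controls of both lines. Pana drought library 3 lay with the controls on this component: across genes it correlated best with PI 567690 control library 1 (r = 0.938), and its highest correlation within its own group was 0.863. Pana drought libraries 1 and 2 correlated best with PI 567690 drought library 1 (r = 0.92 and 0.936). Pana control library 1 stood apart from all others on the second component, which held 27.1% of the variance. PI 567690 drought libraries 2 and 3 were close to identical (r = 0.992): the median chi-square of their recovered reads was 0.87 to 1.4 times that of sampling noise over 4 ranges of read number, against 1.23 or more for every other pair of replicates. They exceeded sampling noise at the highest read numbers and were kept as 2 libraries, and the counts with both averaged into 1 library are given beside the results.

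**Figure D1:**
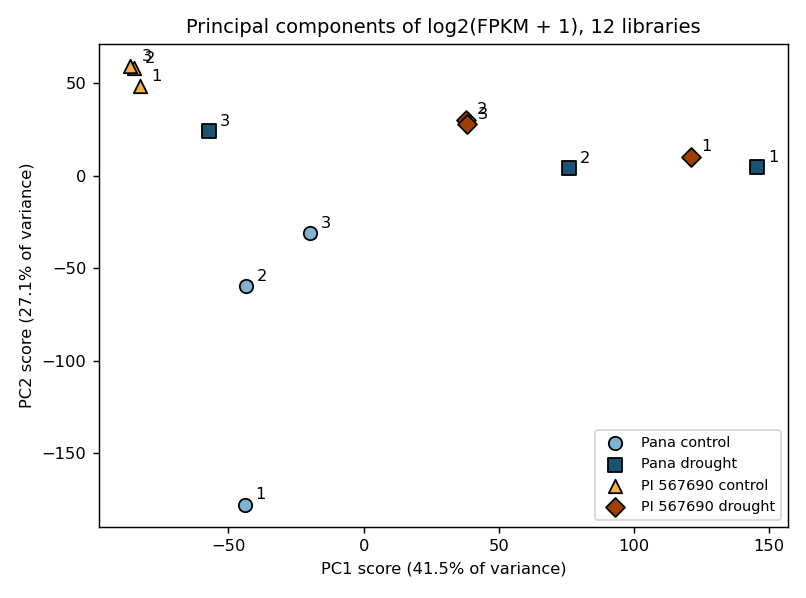
Scores of the 12 libraries on the first 2 principal components of log2(FPKM + 1), with 41.5% (horizontal axis) and 27.1% (vertical axis) of the variance; each point is 1 library, and numbers are replicate numbers. Pana drought library 3 (score -57.3 on the first component) lies on the side of the controls, and Pana control library 1 (score -177.9 on the second) lies apart from the rest.

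The first comparison asked which genes changed under drought in the susceptible line. In Pana, 704 of 32697 genes changed (limma, adjusted p under 0.05), 489 of them higher and 215 lower under drought, with a median absolute log2 fold change of 1.71. Glyma20g29770 rose from 3.42 ± 0.908 to 576 ± 567 FPKM (mean ± SD, n = 3; log2 fold change 5.88 ± 1.05 SE, adjusted p = 0.0212). Glyma01g42840 rose from 2.35 ± 1.39 to 164 ± 155 FPKM (log2 fold change 5.26 ± 0.64 SE, adjusted p = 0.00382). Both were also higher under drought in PI 567690, with log2 fold changes of 5.25 and 3.71 (adjusted p = 0.00894 and 0.00441), and the tests of the difference between the lines did not pass (log2 difference -0.63 and -1.55, adjusted p = 0.849 and 0.388). The largest fall was that of Glyma02g37990, from 462 ± 315 to 9.06 ± 7.07 FPKM (log2 fold change -5.69 ± 0.72 SE, adjusted p = 0.0047). Next came that of Glyma14g37440, from 529 ± 436 to 14.9 ± 14.7 FPKM (log2 fold change -5.33 ± 0.9 SE, adjusted p = 0.0171).

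The size of the Pana response depended on single libraries. It was 8257 genes without Pana drought library 3 and 5332 without Pana control library 3. It lay between 184 (without Pana control library 2) and 358 (without Pana drought library 2) when Pana drought library 1, any PI 567690 control library or PI 567690 drought library 2 or 3 was left out instead. With the 6 Pana libraries fitted alone limma called 0 genes, while 4054 had an unadjusted p under 0.05. With PI 567690 drought libraries 2 and 3 averaged it called 284. The fit over all 12 libraries uses 1 spread per gene. The median SD was smaller in PI 567690 (0.139 and 0.213) than in Pana (0.426 and 0.427). The p-values and SEs of the Pana contrast in that fit can therefore be too small. The call of Glyma20g29770 was lost without Pana control library 2, Pana drought library 1 or Pana drought library 2 (adjusted p = 0.0739, 0.0547 and 0.0672), and that of Glyma14g37440 without Pana control library 2 or without both Pana drought libraries 1 and 3 (adjusted p = 0.0681 and 0.0962). Over all settings their adjusted p ranged from 7.06e-05 to 0.284 and from 0.00805 to 0.205. Scaling the libraries to an equal median ratio moved the median log2 fold change of all tested genes from 0.32 to 0.1. It gave 703 genes, 361 higher and 342 lower, so the share of rises went from 69.5% to 51.4%, and 560 of the 704 genes kept their call and direction.

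The same comparison in the tolerant line gave 4023 genes, 1981 higher and 2042 lower under drought, or 12.3% of those tested. In the fit over all 12 libraries, 9820 genes in PI 567690 and 9701 in Pana had an unadjusted limma p under 0.05. The gap between 4023 and 704 calls thus arises at the adjusted threshold. It does not by itself show a broader response in PI 567690. Glyma20g34670 rose from 20 ± 6.55 to 7830 ± 3600 FPKM in PI 567690 (log2 fold change 8.45 ± 1.47 SE, adjusted p = 0.00448). It reached 1519, 4.542 and 28.39 FPKM in the 3 Pana drought libraries, against 1.04 ± 0.0284 FPKM in the Pana controls (log2 fold change 4.94, adjusted p = 0.0838). Glyma09g31740 went from 5.79 ± 0.315 FPKM to 9391, 281.6 and 288.4 FPKM (log2 fold change 7.08 ± 2.04 SE, adjusted p = 0.0441). In Pana it went from 21.5 ± 1.98 FPKM to 29040, 4488 and 27.41 FPKM (log2 fold change 6.11, adjusted p = 0.101), and the test of the difference did not pass (log2 difference 0.97, adjusted p = 0.883). Among the genes that fell, Glyma17g32100 went from 723 ± 67.6 to 2.22 ± 0.662 FPKM (log2 fold change -7.83 ± 1.67 SE, adjusted p = 0.0121). Glyma08g08761 went from 228 ± 50.7 to 0.675 ± 0.267 FPKM (log2 fold change -7.08 ± 1.45 SE, adjusted p = 0.0101). In Pana drought library 3 both stood at 369.2 and 62 FPKM, while Pana drought libraries 1 and 2 held 0.3144 FPKM or less of each.

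The PI 567690 count was also set in part by other libraries, through the spread they share in the fit. It rose to 7058 without Pana drought library 3 and to 6436 without Pana control library 1. It fell to 2075, 1700 and 1582 without PI 567690 control library 1, 2 or 3 and to 1724, 2170 and 2113 without PI 567690 drought library 1, 2 or 3. With the 6 libraries of PI 567690 alone it was 14731, and with drought libraries 2 and 3 averaged 2149. Scaling to an equal median ratio moved the median log2 fold change of all tested genes from 0.21 to -0.03. It gave 3931 genes, 1277 higher and 2654 lower, so that rises made up 32.5% in place of 49.2% of the calls, and 3306 of the 4023 genes kept their call and direction. At a mean of at least 5 FPKM it was 1504, 976 higher and 528 lower. Glyma09g31740 lost its call under that scaling (adjusted p = 0.0502), without PI 567690 control library 1, 2 or 3 (0.112, 0.121 and 0.125). It was also lost without PI 567690 drought library 1, 2 or 3 (0.184, 0.0677 and 0.0692). Without Pana control library 2 or 3 or Pana drought library 2 its adjusted p was 0.0626, 0.0593 and 0.0555. With no filter on low values it was 0.0648, at a mean of at least 5 FPKM 0.056, and with PI 567690 drought libraries 2 and 3 averaged 0.0689. The call was kept in 9 of 23 settings, over a range of adjusted p from 0.00211 to 0.184. Glyma17g32100 lost its call without PI 567690 drought library 1 (adjusted p = 0.0502, range 8.11e-07 to 0.0502 in all settings) and, with limma's voom on recovered reads, at an adjusted p of 0.0501. Glyma08g08761 had an adjusted p of 0.0553 with voom, the highest of a range from 2.24e-05.

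**Figure D2:**
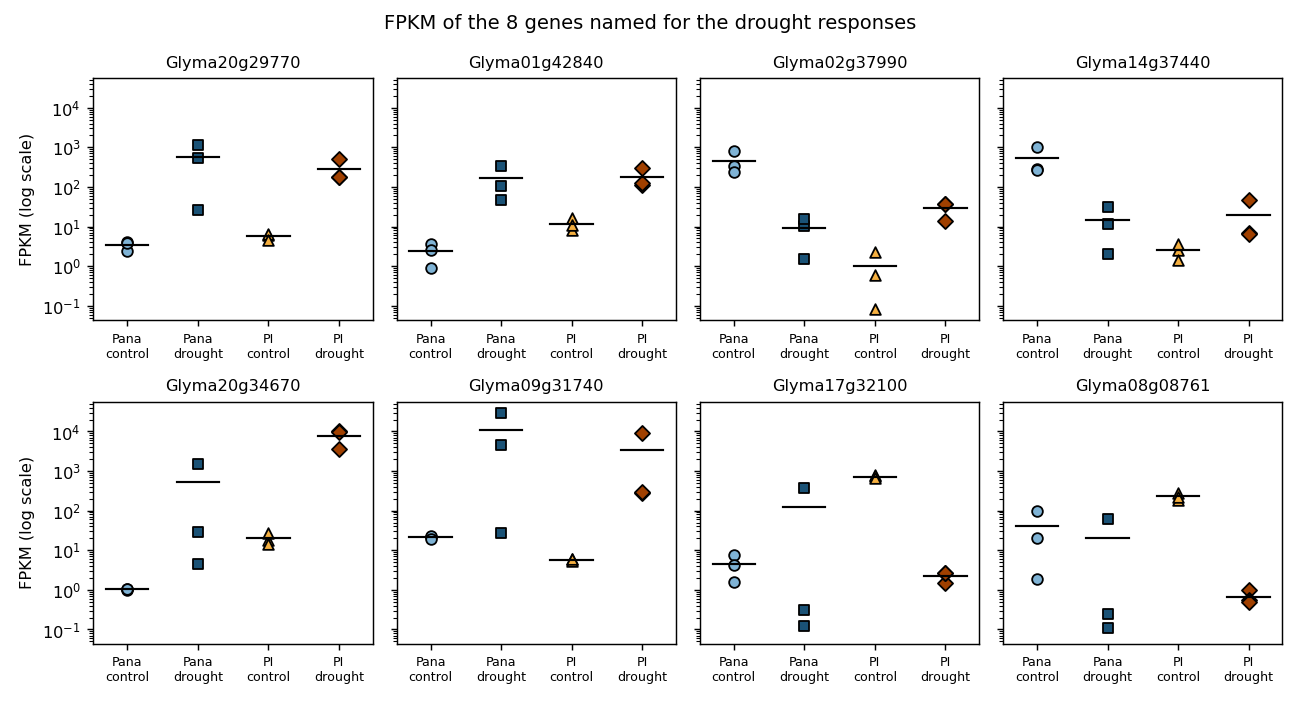
FPKM (vertical axis, log scale) of the 8 genes named for the drought responses in each of the 12 libraries; points are single libraries by group (horizontal axis) and horizontal bars are arithmetic means of 3 libraries. Glyma17g32100 and Glyma08g08761 are low in all 3 PI 567690 drought libraries, and Pana drought library 3 is the highest of its group for both (369.2 and 62 FPKM).

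The genes called in both lines were compared next. No control library is shared between these 2 contrasts, but each gene has 1 estimate of its spread for both, which raises the overlap of calls in either direction above that of independent lists. In both lines 119 genes rose, against 29.6 for independent lists, and 38 fell, against 13.4, while 57 changed in opposite directions, against 43.6. Across all tested genes the 2 responses had a Pearson correlation of 0.3 and a Spearman correlation of 0.25 (across genes, which are not independent replicates). Of the 4023 genes called in PI 567690, 56.4% had the same sign in Pana, below the 64% of all tested genes. The 157 shared calls became 2475 without Pana drought library 3 and 413 without Pana control library 3. They were 48 without Pana control library 2, 63 and 57 without Pana drought library 1 or 2, 50, 41 and 36 without PI 567690 control library 1, 2 or 3, and 61, 45 and 47 without PI 567690 drought library 1, 2 or 3. With PI 567690 drought libraries 2 and 3 averaged 46 were shared, and with each line fitted alone limma called 0 genes in Pana (4054 at an unadjusted p under 0.05) and 0 were shared.

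Taken library by library, the genes that rose in PI 567690 had a median log2 ratio to the Pana controls of 0.7 and 0.69 in Pana drought libraries 1 and 2 and of -0.04 in Pana drought library 3. The genes that fell in PI 567690 had medians of -0.14 and 0 in Pana drought libraries 1 and 2, and of 0.62 in library 3. These falling genes had a median of 0.992 FPKM in the Pana controls, against 5.86 FPKM in the PI 567690 controls. In the Pana controls 50.3% of them were below 1 FPKM, which limits how far those could fall there. The median room to fall over all of these genes was 0.99 on the log2(FPKM + 1) scale. Genes with more room were not examined separately, so the low level was not tested as the reason for the medians in Pana. In the PI 567690 drought libraries, from which the genes were chosen, the medians were 1.6, 1.3 and 1.31 for the rising genes and -1.79, -1.46 and -1.46 for the falling ones.

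**Figure D3:**
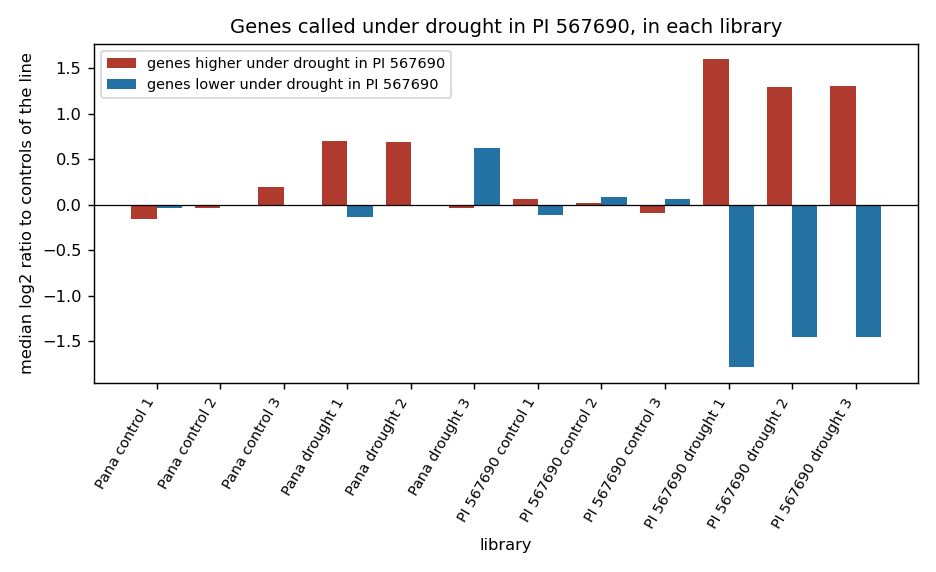
Median log2 ratio (vertical axis) of the 1981 genes higher and the 2042 genes lower under drought in PI 567690, in each of the 12 libraries (horizontal axis); drought libraries are set against the 3 controls of their line, and each control library against the other 2. The rising genes reach medians of 0.7 and 0.69 in Pana drought libraries 1 and 2 and -0.04 in library 3.

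Whether the lines differed in their response was tested directly as the difference of the 2 drought effects. It passed in 1829 genes, with a positive difference (PI 567690 minus Pana) in 444 and a negative one in 1385. A negative difference can be a fall in PI 567690 that Pana did not show, so it need not mean a weaker response. The difference also equals the line difference under drought minus that under control. Genes higher in PI 567690 under control (3739 of 4762 called) can therefore enter as negative differences where the lines differ less under drought. Among genes with a mean of at least 5 FPKM the split by sign was closer to even, 176 positive and 229 negative. Glyma02g37990 had the largest positive difference (log2 9.65 ± 1.02 SE, adjusted p = 0.00145): it fell in Pana, as given above, and rose in PI 567690 from 0.982 ± 1.13 to 29.2 ± 13.5 FPKM (log2 fold change 3.96, adjusted p = 0.00573). Glyma15g06816 likewise fell in Pana from 37.6 ± 34.8 to 1.68 ± 0.738 FPKM and rose in PI 567690 from 0.619 ± 0.441 to 37.8 ± 4.78 FPKM (difference 8.13 ± 0.69 SE, adjusted p = 0.000491). The largest negative differences were those of Glyma17g37900 (log2 -8.91 ± 1.6 SE, adjusted p = 0.00999) and Glyma08g18200 (log2 -8.4 ± 1.29 SE, adjusted p = 0.00591). Glyma17g37900 fell in PI 567690 from 340 ± 39.7 to 1.85 ± 1.03 FPKM. In Pana it was at 0.138 ± 0.0479 FPKM in the controls and at 0.2546, 0.1434 and 55.73 FPKM in the drought libraries (log2 fold change 1.93, adjusted p = 0.261). Glyma08g18200 fell in PI 567690 from 857 ± 507 to 14.8 ± 2.5 FPKM. In Pana it was at 5.76 ± 2.41 FPKM in the controls and at 32.92, 8.624 and 266.7 FPKM under drought (log2 fold change 2.78, adjusted p = 0.0984). All 4 kept their calls in each setting run for them, which for Glyma02g37990, Glyma15g06816 and Glyma17g37900 leaves out voom. The count was 1104 without Pana control library 2, 876 and 786 without PI 567690 control library 2 or 3, 1131, 982 and 981 without PI 567690 drought library 1, 2 or 3, and 992 with PI 567690 drought libraries 2 and 3 averaged.

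**Figure D4:**
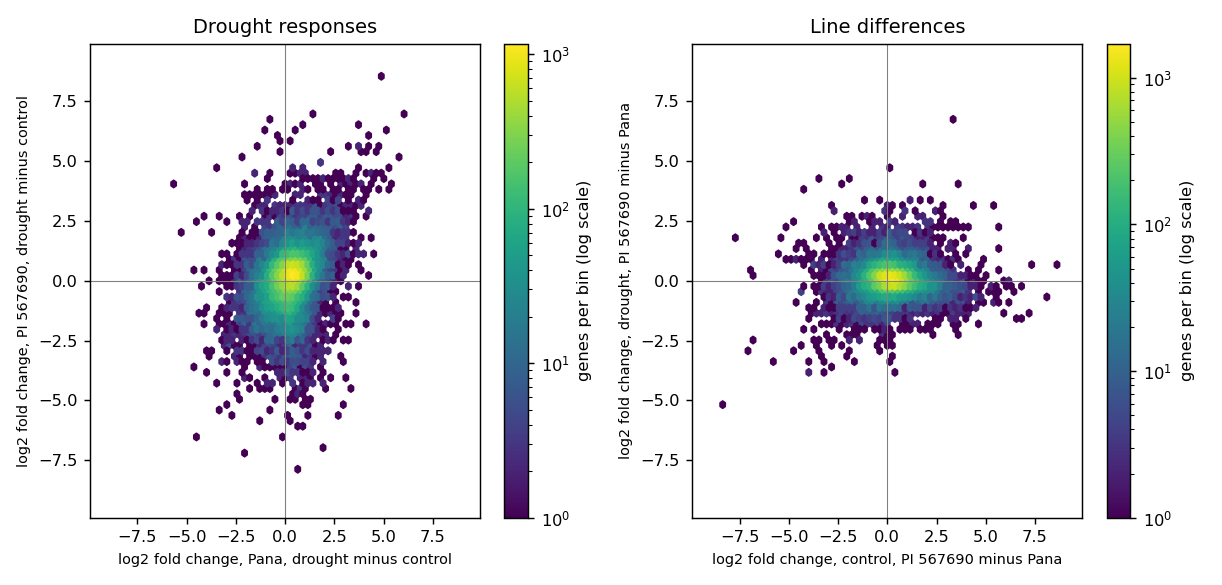
Log2 fold changes of the 32697 tested genes, binned, with colour giving the number of genes per bin on a log scale. Left: drought minus control in Pana (horizontal axis) and in PI 567690 (vertical axis), correlated across genes at r = 0.3; right: PI 567690 minus Pana under control (horizontal axis) and under drought (vertical axis), where 4762 and 127 genes passed the test.

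Well-watered plants of the lines differed in 4762 genes, 3739 higher and 1023 lower in PI 567690. Glyma11g10460 stood at 944 ± 72.2 FPKM in PI 567690 and 1.61 ± 1.11 FPKM in Pana (log2 fold change 8.58 ± 1.86 SE, adjusted p = 0.0099). Under drought its levels overlapped between the lines, at 0.624, 18.04 and 591.2 FPKM in Pana and 2.01, 161 and 138.5 FPKM in PI 567690. Glyma17g37900 stood at 340 ± 39.7 and 0.138 ± 0.0479 FPKM (8.22 ± 1.13 SE, adjusted p = 0.000935). In the other direction, Glyma09g15450 stood at 3.3 ± 1.69 FPKM in PI 567690 and 2360 ± 2940 FPKM in Pana (log2 fold change -8.25 ± 0.96 SE, adjusted p = 0.000423). Glyma02g37990, named above for its opposite drought responses, was also lower in PI 567690 (-7.81 ± 0.72 SE, adjusted p = 0.000138). All 4 kept their calls in each setting run for them, which leaves out voom. The count was 2482 without PI 567690 control library 2 and 2564 without library 3, and 3897 with PI 567690 drought libraries 2 and 3 averaged. The share of genes higher in PI 567690 was 78.5%, or 71.3% after scaling, which moved the median log2 fold change of all tested genes from 0.2 to 0.12. The balance turned with abundance: 0 genes were higher and 6 lower in PI 567690 among the 100 with the highest mean FPKM, 13 and 58 among the next 900, 453 and 365 among the next 9000, and 3273 and 594 among the remaining 22697.

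Genes that differed between the lines under control overlapped with the drought response of PI 567690. Of the 3739 genes higher in PI 567690 controls, 1490 (39.9%) fell under drought in that line, against 233.5 for independent lists, and 29 rose. Of the 1023 lower genes, 328 rose and 6 fell. Both contrasts use the same PI 567690 control libraries, which alone bring a negative relation: simulated groups with no effect gave a covariance of -0.097 across genes, against -0.484 observed. The correlation across genes was -0.59, against -0.5 simulated. With separate PI 567690 control libraries for the 2 contrasts, 1 for one and 2 for the other, the covariance was -0.49 to -0.418 over the 6 ways to divide them. Part of the overlap of calls can still come from the shared controls, since the counts were not taken with separate ones.

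Under drought the lines differed in 127 genes, 95 higher and 32 lower in PI 567690. Glyma15g06780 stood at 134 ± 14.4 FPKM in PI 567690 and 7.24 ± 4.25 FPKM in Pana (log2 fold change 4.2 ± 0.6 SE, adjusted p = 0.00998). It was the only named gene of this contrast that passed the test of the difference of drought responses (log2 difference 6.13, adjusted p = 0.00423). Glyma11g21756 was higher in PI 567690 under drought, 31.8 ± 17.3 against 0.722 ± 0.485 FPKM (4.09 ± 0.41 SE, adjusted p = 0.000778), and stood at 16.4 ± 1 against 0.515 ± 0.233 FPKM in the controls. Glyma18g20990 (0.112 ± 0.0295 against 19.3 ± 16.4 FPKM; log2 fold change -3.9 ± 0.51 SE, adjusted p = 0.00546) and Glyma11g01160 (3.75 ± 1.35 against 67.1 ± 18.2 FPKM; -3.85 ± 0.49 SE, adjusted p = 0.00398) were lower in PI 567690. The count was 191 without Pana control library 1 and 59 and 63 without PI 567690 drought library 2 or 3, 65 with those 2 averaged and 40 with the 6 drought libraries alone. Without Pana drought library 3 it was 188, 98 higher and 90 lower, and after scaling 106, 71 higher and 35 lower. At a mean of at least 5 FPKM it was 24, 13 higher and 11 lower. Glyma15g06780 lost its call without PI 567690 drought library 2 or 3 (adjusted p = 0.0585 and 0.0517), over a range of 0.00205 to 0.155 in all settings. With the drought libraries alone Glyma11g21756 and Glyma18g20990 lost theirs (adjusted p = 0.0903 and 0.0969, ranges 5.8e-05 to 0.0903 and 0.00107 to 0.0969), and without Pana drought libraries 1 and 3 Glyma11g01160 did (0.0845, range 0.000206 to 0.0845).

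Genes that part the lines in all other libraries were then read in each library left out of their choice. In Pana drought library 1, 44.8% of 134 such genes were at the Pana level and 35.8% at the PI 567690 level, and in Pana drought library 3 the shares were 56.3% and 23.3% of 103 genes. In the other 4 Pana libraries 79.3% to 93.2% were at the Pana level and at most 4.9% at the PI 567690 level. In the 6 PI 567690 libraries 63.6% to 98.6% were at the PI 567690 level and at most 12.1% at the Pana level. The 63.6% and the 12.1% were both those of PI 567690 drought library 1 (99 genes). The other PI 567690 libraries had 82.9% to 98.6% at their own level and at most 3.8% at the Pana level. Without Pana drought libraries 1 and 3 the drought response was 1049 genes in Pana and 7549 in PI 567690, and the difference of the responses passed in 1111 genes.

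**Figure D5:**
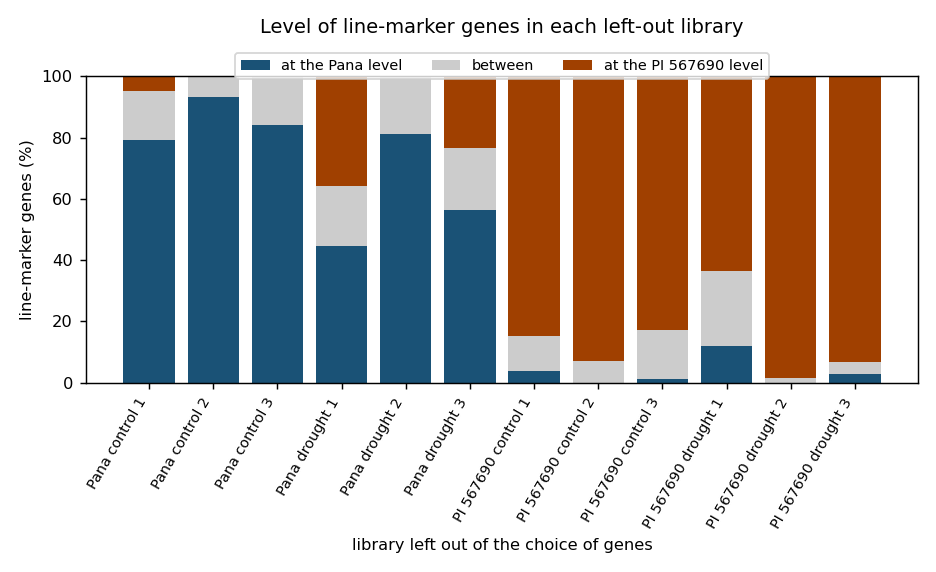
Share of line-marker genes (vertical axis, %) at the level of Pana, at the level of PI 567690 or between, in each of the 12 libraries (horizontal axis), with the genes chosen from the other libraries. Pana drought libraries 1 and 3 have 35.8% and 23.3% of these genes at the PI 567690 level, against at most 4.9% in the other Pana libraries.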

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

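The tests of explanations and the counts over other splits of the libraries in this part were chosen after the results they bear on had been seen.

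The difference between the drought responses of the lines, tested as an interaction, passed in 1829 genes, and 6 of the named genes are among them. The log2 differences (PI 567690 minus Pana) were 9.65 for Glyma02g37990, 8.13 for Glyma15g06816, 7.35 for Glyma14g37440 and 6.13 for Glyma15g06780, and -8.91 for Glyma17g37900 and -8.4 for Glyma08g18200. Of 100 splits of the libraries drawn within treatments, 3 gave as many genes, the real one included, but these splits also mix the lines themselves and so do not test the difference of responses alone. With the additive effects of line and treatment removed first, the real split gave 1772 genes and was the only 1 of 100 as large (highest other 1). The values left after that step still hold the real difference of responses, which widens the spread within the groups of every other split. That lowers their counts, so this comparison does not exclude chance. It also counts the near-identical PI 567690 drought libraries 2 and 3 as separate samples. The highest of the other splits before the additive effects were removed gave 6573 genes, several times the real count. It set Pana drought library 3 with PI 567690 drought libraries 2 and 3 but kept the lines apart in the controls. The real split groups the controls in the same way, so the line difference under control (4762 genes called) enters both counts. The 2 splits differ only in the drought libraries, so the higher count comes from how these were grouped.

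Pana drought libraries 1 and 3 had part of the genes that separate the lines at the level of PI 567690. A library of PI 567690 under a wrong name is argued against, since at least 44.8% of these genes were at the Pana level in each of them, against at most 12.1% in any PI 567690 library. RNA of PI 567690 mixed in stays open. Of the genes higher in Pana, 36.7% and 33.3% were at the PI 567690 level in libraries 1 and 3 (at most 11.1% in the other Pana libraries). Mixing alone would need a share of at least 88% and 89% for this. The genes higher in PI 567690 that stayed at the Pana level allow at most 11% and 9%. Pana control library 1 gave the same mismatch, with 86% needed and 6% allowed, at 11.1% of the genes higher in Pana. Variation between Pana libraries can thus produce it, so the mismatch does not decide on mixing. Plants that carry chromosome segments of the other line may be a further explanation, but neighbouring marker genes shared their state no more often than shuffled ones in library 1 (permutation p = 0.87), and in library 3 they did so with p = 0.027, or 0.054 adjusted for 2 libraries, so this stays open. A drought response of Pana that varies between plants and reaches these genes was not tested and stays open too.

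PI 567690 drought libraries 2 and 3 differed far less than other replicates. One RNA sequenced as 2 libraries is consistent with their median chi-square of 1.13 times sampling noise at 100 to 500 reads, where the next closest pair had 1.96. Plants that were alike beyond the other replicates stay open, since no label says which plants were taken.

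More genes differed between the lines under control (4762) than under drought (127). The fit gives each gene the same SE in both contrasts (median 0.31), so a larger spread among the drought libraries lowers both counts in it. Without Pana drought library 3 the counts were 6144 and 188, and with only the compared groups in the fit 4998 and 40. The median SD of a gene was 0.426 under control and 0.427 under drought in Pana, and 0.139 and 0.213 in PI 567690. Scaling is argued against by the 5032 genes under control and 106 under drought after it, and without Pana drought libraries 1 and 3 the counts were 6333 and 167, with 1 Pana drought library left. Smaller differences between the lines under drought may be a biological explanation, as a hypothesis found on these data, but they stay open: with within-group spread subtracted, the variance of the line differences was 0.613 under control and -0.008 under drought, and the first exceeded 1.5 times the second by 0.624 ± 0.355 (jackknife SE), which is under 2 SE. A difference in growth stage or in the state of the control plants was not tested and stays open too.

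The remaining counts have too few splits for a share under 0.05, with 10 each. For drought in Pana, 2 splits gave as many genes, the real one with 704 and another with 1224, which set Pana control library 1 with Pana drought libraries 1 and 2. For drought in PI 567690 the real split was the only 1 as large (4023, highest other 1), as it was for the lines under control (4762, highest other 1). For the lines under drought, 2 splits gave as many, the real one with 127 and another with 2066, several times as many. The latter set Pana drought libraries 1 and 2 with PI 567690 drought library 1, which points to a structure of the drought libraries beyond their line.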

How the results depend on the processing

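The tests of the comparisons, the filters and most alternatives were chosen before the data were examined. The averaging of 2 PI 567690 drought libraries, both leave-outs of 2 libraries and voom were added afterwards, as were the tests of explanations, except the shuffling of calls between neighbouring genes. The 6 counts are given in the order drought in Pana, drought in PI 567690, difference of responses, lines under control, lines under drought and shared drought calls. A mean of at least 5 FPKM gave 328, 1504, 405, 1400, 24 and 73, with fewer genes tested (17787). An adjusted p under 0.01 gave 85, 1402, 486, 2228, 64 and 9. Voom on recovered reads gave 392, 1914, 803, 2847, 52 and 72, with 21431 genes tested. Averaging PI 567690 drought libraries 2 and 3 gave 284, 2149, 992, 3897, 65 and 46. Leaving out Pana control library 1 and Pana drought library 3 gave 10233, 11918, 2992, 6478, 437 and 4429, and leaving out Pana drought libraries 1 and 3 gave 7549 in PI 567690, 1111 for the difference and 640 shared calls. With no filter, 395 genes were called in Pana and 79 were shared. With only the compared groups in the fit, limma called 0 genes in Pana (4054 at an unadjusted p under 0.05), 14731 in PI 567690, 40 between the lines under drought and 0 shared. Leaving out 1 library gave 184 to 8257, 1582 to 7058, 786 to 2290, 2482 to 7075, 59 to 191 and 36 to 2475 in the same order. Where 1 library is left, it is assumed to vary like the others. Where neither fewer genes nor fewer libraries account for a change, the cause was not tested.

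Scaling to an equal median ratio, a pseudocount of 0.1 and a 2-fold minimum kept every count within 1.5 times. So did the replicate block, with 533, 4676, 2059, 5218, 108 and 128. Replicate numbers did not clearly pair the libraries. Deviations of same-numbered libraries correlated at -0.11 to 0.66, above 0.1 in 5 of 18 pairs, and 6 of 12 libraries correlated best with their own number. The highest value, 0.66, joined drought libraries 1 of both lines. Drought libraries 3 correlated at 0.61, but Pana drought library 3 also reached 0.6 with PI 567690 drought library 2. An effect shared by same-numbered drought libraries is not excluded. Of 467 values of named genes under alternatives, 430 kept their call, 37 kept their direction only and 0 reversed. The alternatives planned for a table of counts were not run, because the table holds FPKM, nor were the gene list tests, because no identifier matched a description. Genes with a mean of 1 to 2 FPKM had the fewest reads in Pana control library 1, with a median of 15.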

Other observations

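The 100 genes with the highest mean FPKM had a median log2 fold change under drought of -1.1 in Pana and -1.19 in PI 567690 (-1.43 and -1.5 after scaling), while 1 of them was called lower in Pana and 3 in PI 567690, and 1 and 11 were called higher. The next 900 genes had medians of -0.26 in Pana and 0.17 in PI 567690 (-0.58 and -0.13 after scaling), with 9 called higher and 14 lower in Pana and 95 higher and 21 lower in PI 567690. The next 9000 had medians of 0.19 and 0.31 (-0.12 and 0.02 after scaling), with 142 called higher and 55 lower in Pana and 704 higher and 305 lower in PI 567690. The remaining 22697 had medians of 0.38 and 0.18 (0.18 and -0.04 after scaling), with 337 called higher and 145 lower in Pana and, turning the other way, 1171 higher and 1713 lower in PI 567690. The 100 most abundant genes of each library took 27.63% to 40.7% of the FPKM total in the Pana controls and 23.77% to 31.8% under drought, with Pana drought library 3 the highest of its group, and 32.77% to 34.1% and 19.97% to 27.07% in PI 567690.

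Some genes switched between off (below 0.5 FPKM in all 3 libraries) and on (at least 5 FPKM in all 3). In PI 567690, 48 genes were on under drought alone and 66 under control alone; in Pana these were 2 and 1. Between the lines, 95 genes were on in PI 567690 alone and 27 in Pana alone under control, against 3 and 3 under drought. Because all 3 libraries must pass, Pana drought library 3, which lay with the controls, can by itself keep a gene from counting. PI 567690 drought libraries 2 and 3 were close to identical, which makes the rule easier to meet there. These counts therefore do not compare the lines or the treatments on equal terms.

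The shuffling test of the following hypothesis was set before its result was seen, and the comparison with as many drought genes afterwards. Genes that differ between the lines whatever the treatment may lie next to each other more often than chance, as segments of different descent would place them. In the order of their identifiers, which carry a chromosome number, 74 genes differed in the same direction under control and under drought, and 5 neighbouring pairs of tested genes were both among them, 64.9 times the 0.1 of shuffled calls (permutation p = 0.001, the smallest that 1000 shuffles can give). In 1000 draws of 74 genes from the drought calls of PI 567690, at most 3 pairs were found, and 0 among the 74 with the smallest p. All genes that differed between the lines under control gave 639 pairs against 457.7 shuffled, a factor of 1.4, below the 1.7 of the drought calls (430 against 246), lists too long to compare with the short one. The result is consistent with the hypothesis for differences kept in both treatments but rests on 5 pairs, and pairs of tandem gene copies that share reads would give the same picture and were not separated from it.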
